A study of Mus musculus with 20 samples.

How the data were processed

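Whole lymph nodes of Rag1-deficient mice aged 9 weeks were analysed as bulk polyA RNA in 20 libraries, 4 from each of 5 positions: duodenal, jejunal, ileal, ceco-colonic and inguinal. Per the labels' protocols, RNA was isolated with the PicoPure kit and libraries were prepared with a NEBNext poly(A) kit. The labels number the libraries of each position from 1 to 4 without saying whether a number stands for an animal, so the numbers were not treated as pairs. Per the submitters' processing notes, kallisto, limma and edgeR were used with the builds GRCm39 and mm10, and the role of each build and the versions are not given in the sources used here.

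The deposited gene table holds expected counts, that is, estimated counts per gene for 56258 genes, of which 135 lack a symbol. The deposited transcript tables, 1 per library, hold estimated counts (expected counts) and TPM for 149419 transcripts. Genes of the transcript tables numbered 56691, and 56033 were shared with the gene table. The gene table was checked against the transcript tables over 12542 genes with at least 500 estimated counts. Length-scaled TPM summed per gene gave 99.5% of its values within 0.001 on the log2 scale (median difference 1.58e-05), whereas plain sums of estimated counts gave 3.34%. The values tested are thus estimates scaled by transcript length, not raw read counts. Of its gene identifiers 51489 occurred in the GRCm38 reference used here, 47195 of them with the same symbol. Only 35 versioned identifiers of the transcript tables matched that reference, so no coordinates are given.

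Gene estimates were rounded and tested with edgeR 4.0.16 (R 4.3.3) after filterByExpr by position (minimum count 10, minimum total 15), which kept 29411 genes, and TMM normalization. A single quasi-likelihood fit of all 20 libraries with 1 mean per position gave every comparison. The tagwise prior had 4.47 degrees of freedom and the median biological coefficient of variation was 0.157. The comparisons were an F-test among the 4 gut positions, gut-draining nodes (mean of 4 positions) against inguinal, small intestinal nodes (mean of 3 positions) against ceco-colonic, each gut position against inguinal, and the 6 pairs of gut positions. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. CPM (counts per M) are TMM-scaled with SD over libraries, and log2 CPM used a prior count of 2. The standard error of log2 fold changes is model-based and can understate spread at low CPM. Variance between positions was tested by permuting labels.

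Lists of known genes, 27 with 378 distinct symbols, were written before the data were examined, as were the comparisons and the rule for naming genes. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01 in 12 comparisons, and its members were counted as called over all genes and, separately, with adjustment over the list alone. Camera p-values were adjusted over the lists of a comparison. The preset correlation makes camera sensitive to genes that move together between libraries, so its p is followed by the one with a correlation estimated from the data wherever that ended a call.

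The rule named 22 fixed genes. It added the 8 highest and 8 lowest fold changes in gut-draining against inguinal, small intestinal against ceco-colonic, duodenal against ileal and duodenal against ceco-colonic nodes, and 4 of each in the other pairs. These had to be called, reach 5 CPM in the higher group and show no overlap between the libraries of the groups. It further added the 8 smallest p of the F-test and up to 3 called members per list, or the 2 most abundant where none was called. Model names and receptor segments were left out. The rule names 246 genes, of which 114 are given here, chosen for what they show of the biology and partly with their behaviour under the alternatives already known. Some of the others are not reported here.

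Depth was 148.2 to 304.6 M (mega counts) estimated counts per library. The most abundant gene, Gm19220, took 2.44% to 6.41% of a library and mitochondrial genes 1.15% to 2.41%. The procedure was tested on 100 simulated changed genes of each size among 29411. It recovered 66% of 1.5-fold and 91% of 2-fold changes for duodenal against ileal, 83% and 98% for gut-draining against inguinal, 74% and 99% for small intestinal against ceco-colonic, and 75% and 90% for jejunal against ileal. False calls were 1.88%, 2.69%, 5.98% and 2.94% of calls. Recovery at low levels was not tested apart. Reads of near-identical genes (the Mup family, Amy2a1 to Amy2a5, Try4 and Try5, the Ccl21 family and the hemoglobin genes) cannot be told apart with certainty.

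Alternatives chosen before the data were examined were size factors of the DESeq2 type, no filter on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, counts summed from transcripts, and fits of only the groups compared. For lists they were camera with an estimated correlation, fry, and camera with the replicate block. For the variance between positions they were the 500 most variable genes and a prior count of 0.5. Leaving out duodenal libraries 1 and 2 and adding the mean log2 level of the adipocyte list as a covariate were chosen after the data were seen. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9. Sequencing reads were not analysed here.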

Results

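RNA was sequenced from whole lymph nodes of 9-week-old mice lacking a functional Rag1 gene, in which T and B lymphocytes do not mature. Nodes from 5 positions gave 4 libraries each: those draining the duodenum, the jejunum, the ileum, and the cecum with the colon, and the inguinal node, which drains skin and is the reference outside the gut. The labels do not say whether the 4 libraries of a position came from separate animals, so p-values measure only the spread between these libraries. Total estimated counts per library (in M, mega counts) were 189.4 to 227.9 in duodenal, 176.1 to 304.6 in jejunal, 184 to 213.2 in ileal, 171.1 to 273.3 in ceco-colonic and 148.2 to 294.2 in inguinal nodes. Between 35159 and 37487 genes had a count in a library. At this depth a level of 1 CPM (1 count per M) stands for at least 148 counts, so the lowest levels given here rest on few counts. The position of the node accounted for 47.4% of the variance in log2 CPM among the 20 libraries and for 37.5% among the 16 gut libraries. Both had a permutation p of 1e-05, the smallest the permutations could give.

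**Figure D1:**
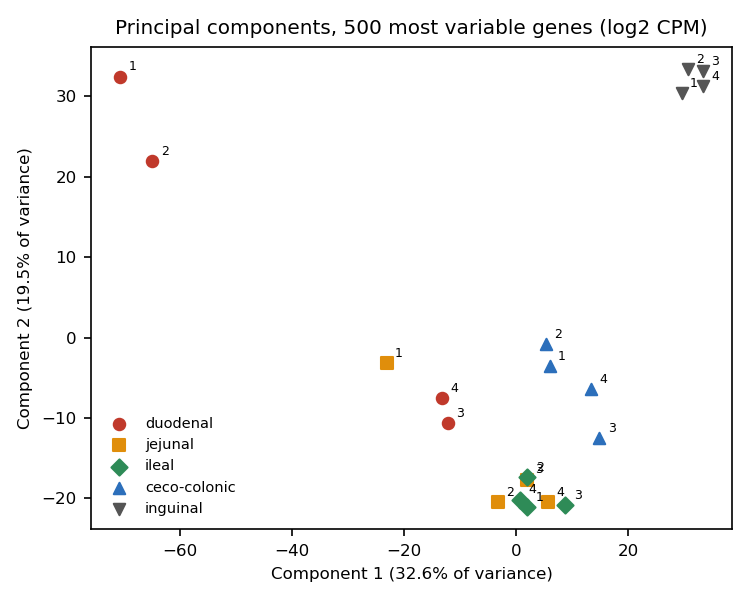
Principal components of log2 CPM over the 500 most variable genes, 1 point per library with its number. Component 1 (x, 32.6% of variance) loads most on pancreatic genes, and component 2 (y) holds 19.5%. Inguinal libraries lie upper right and duodenal libraries 1 and 2 far left.

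Rag1 (ENSMUSG00000061311), the mutated gene, was counted in each of the 20 libraries at 1.98 to 3.43 CPM. Its level was 2.495 ± 0.3301 against 3.17 ± 0.252 CPM (mean ± SD, n = 16 gut and 4 inguinal libraries). Every mouse carried the mutation, and counts of the whole gene do not show which part of it was read, so this level checks no label. Rag2, the partner of Rag1 in receptor gene rearrangement, stood at 0.387 ± 0.0861 against 0.375 ± 0.0819 CPM and was not called. Of 17 lymphocyte genes, 2 were higher and 5 lower (3 and 6 adjusted over the list alone), with camera adjusted p = 0.3198. Cd4, which macrophages and lymphoid tissue inducer cells also make, was lower in gut nodes (174 ± 25.97 against 300.4 ± 23.5 CPM). Cd8a, which a dendritic cell subset carries, was lower too (26.8 ± 10.1 against 54.01 ± 3.86 CPM), whereas Ms4a1, which encodes a B-cell antigen, was higher (2.54 ± 1.05 against 0.649 ± 0.07804 CPM). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.00828 for Rag1, 0.896 for Rag2, 8.64e-07 for Cd4, 4.60e-08 for Cd8a and 1.05e-10 for Ms4a1.

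Transcripts of neighbouring tissues differed between libraries. Cpa1, a pancreatic carboxypeptidase, reached 1981 and 1146 CPM in duodenal libraries 1 and 2, against 0.415 and 0.964 CPM in duodenal libraries 3 and 4 and 6.52 CPM in jejunal library 1. Acinar enzyme genes took 4.80% of all CPM in duodenal library 1 and 2.66% in duodenal library 2, while jejunal library 1 held 0.0138% and every other library 0.00303% or less. Adipoq, the adipocyte hormone adiponectin, ranged from 3.92 CPM in duodenal library 1 to 163 CPM in jejunal library 2, and within the inguinal node from 5.81 to 51.8 CPM. Cnn1, a smooth muscle gene, stood at 35.8 and 37.3 CPM in duodenal libraries 2 and 3 and at 0.443 and 4.41 CPM in duodenal libraries 1 and 4.

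Gut-draining nodes were first set against the inguinal node, to ask what distinguishes nodes of the gut from a skin-draining node when mature T and B lymphocytes are absent. Nkx2-3 (ENSMUSG00000044220), a homeodomain transcription factor of gut mesenchyme and vessels, had the highest fold change among called genes at 5 CPM or more. It stood at 21.9 ± 1.54 against 0.0344 ± 0.0162 CPM (mean ± SD, n = 16 and 4), with a log2 fold change 9.42 ± 0.174 (SE). Madcam1 (ENSMUSG00000020310), the mucosal addressin that holds gut-homing lymphocytes on vessels, was higher as well (78.6 ± 33.7 against 3.77 ± 0.231 CPM), as was Aldh1a2 (ENSMUSG00000013584), an enzyme that makes retinoic acid (176 ± 38.5 against 19.4 ± 2.63 CPM). In the other direction, the inguinal node carried Mup22 at 16.5 ± 2.94 CPM and gut nodes at 0.0128 ± 0.0142 CPM, although reads of the near-identical major urinary protein genes cannot be assigned with certainty. Tbx15, a T-box factor of skin and limb mesenchyme, was also higher in inguinal nodes (0.1499 ± 0.0701 against 13.2 ± 1.98 CPM). In all, 7724 of 29411 genes changed, 3931 higher and 3793 lower in gut nodes, and 1764 of them by at least 2-fold. The share of higher calls was 50.9% with edgeR and lay between 49.1% (limma-voom) and 51.6% (DESeq2) over the alternatives. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 3.22e-18 for Nkx2-3, 1.74e-12 for Madcam1, 1.75e-12 for Aldh1a2, 7.55e-17 for Mup22 and 3.15e-16 for Tbx15.

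Genes of retinoid metabolism and response were tested as a list. Of 20 retinoid genes, 9 were higher and 5 lower (10 and 6 adjusted over the list alone), with camera adjusted p = 9.41e-04 and adjusted p = 0.121 with an estimated correlation. Their median log2 fold change was 0.50. Lrat, which stores retinol as esters, rose from 3.04 ± 0.406 CPM in inguinal to 14.5 ± 5.22 CPM in gut nodes (log2 fold change 2.19 ± 0.171 (SE)). Rarb, a receptor that retinoic acid induces, was higher by 1.94 ± 0.194 on the log2 scale (± SE). Cyp26b1, which degrades retinoic acid, moved the other way (32.8 ± 14.99 against 108 ± 28.2 CPM).

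**Figure D2:**
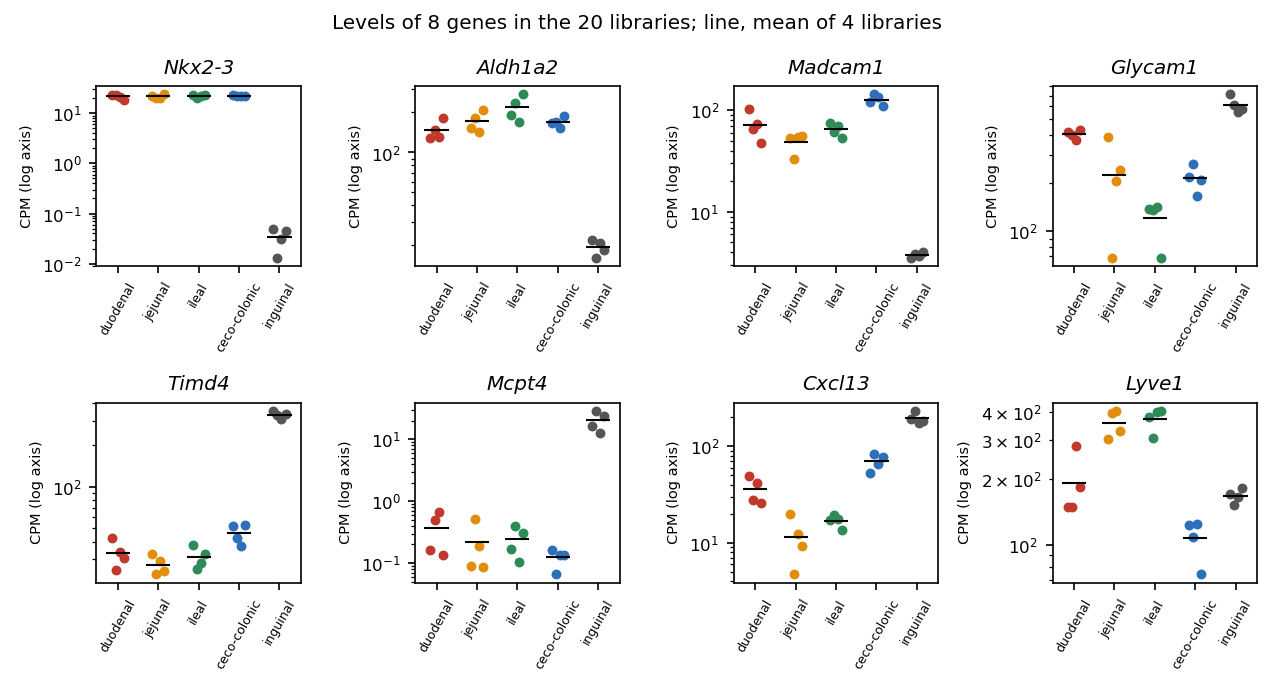
Levels of Nkx2-3, Aldh1a2, Madcam1, Glycam1, Timd4, Mcpt4, Cxcl13 and Lyve1 in CPM on a log axis (y) in each library of the 5 nodes (x), with a line at the mean of 4 libraries. Nkx2-3 has a mean of 0.0344 CPM in the inguinal node and of 21.6 to 22.03 CPM in the small intestinal nodes, and Mcpt4 shows the opposite order.

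Stromal genes were tested as 4 lists. Of 10 medullary reticular cell genes, 5 were higher and 2 lower (5 and 2 adjusted over the list alone), with camera adjusted p = 0.00585 and adjusted p = 0.141 with an estimated correlation. Il33, an alarmin cytokine, was higher in gut nodes (314 ± 40.3 against 147 ± 22.8 CPM). So were Il6, a cytokine that acts on plasma cells (log2 fold change 2.67 ± 0.206 (SE)), and the orphan nuclear receptor Nr4a2 (1.43 ± 0.112). The medullary genes Inmt (144 ± 50.1 against 166 ± 33.8 CPM) and Cxcl12 (1103 ± 79.4 against 1120 ± 102 CPM) were not called. Of 10 T-zone reticular genes, 3 were higher and 2 lower (4 and 3 adjusted over the list alone), with camera adjusted p = 0.593. Ccl21a, a chemokine for cells carrying Ccr7, was higher in gut nodes (2421 ± 760 against 1203 ± 301 CPM), although its near-identical copies share reads. Pdpn, a reticular cell glycoprotein, was higher too (0.69 ± 0.0736), while Tnfsf13b, a survival factor for B cells, was lower (-0.43 ± 0.074). Of 10 follicular and marginal reticular genes, 2 were higher and 3 lower (3 and 3 adjusted over the list alone), with camera adjusted p = 0.952. Cxcl13, the chemokine of B-cell follicles, fell from 196 ± 27.2 CPM in inguinal to 33.6 ± 25.1 CPM in gut nodes. Of 16 fibroblast and matrix genes, 5 were higher and 4 lower (6 and 5 adjusted over the list alone), with camera adjusted p = 0.196. Lum and Fn1, which encode the matrix proteins lumican and fibronectin, were higher (2.22 ± 0.144 and 1.59 ± 0.123). Outside the lists, the matrix genes Mfap4 (5.37 ± 0.41) and Cilp (4.33 ± 0.281), the chemokine Cxcl14 (4.75 ± 0.227) and the neuronal adhesion gene Lrrn2 (4.95 ± 0.138) were among the 8 highest fold changes of called genes at 5 CPM or more. Called genes of this paragraph had adjusted p of 1.59e-04, for Tnfsf13b, or less in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, except Ccl21a, at adjusted p = 2.59e-04.

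Vessel genes were tested as 2 lists. Glycam1 and Chst4, which encode a ligand of L-selectin and the sulfotransferase that completes it in high endothelial venules, were lower in gut nodes (240 ± 123 against 614 ± 71.6 CPM and 9.61 ± 3.79 against 32.7 ± 6.46 CPM). So was Vwf, which encodes von Willebrand factor (-0.96 ± 0.0971 on the log2 scale), while Madcam1, on the same list, was higher. Of 15 blood endothelial and high endothelial genes, 2 were higher and 7 lower (2 and 7 adjusted over the list alone), with camera adjusted p = 0.137. Of 14 lymphatic endothelial genes, 6 were higher and 1 lower (6 and 1 adjusted over the list alone), with camera adjusted p = 0.1996. Foxc2, a transcription factor of lymphatic valves, was higher (3.99 ± 1.302 against 2.15 ± 0.207 CPM) and Nrp2, a co-receptor for lymphangiogenic growth factors, lower (147 ± 23.97 against 193 ± 16.2 CPM). Lyve1, a hyaluronan receptor of lymphatic endothelium, stood at 257 ± 123 against 167 ± 11.9 CPM, and Marco, a scavenger receptor of medullary sinus cells and macrophages, at 1148 ± 374 against 799 ± 111 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.00245 for Marco and 0.0266 for Lyve1. The call of Lyve1 was lost without inguinal library 1, 2 or 3 (adjusted p = 0.0612, 0.0952 and 0.0747) and with the adipocyte level as a covariate (adjusted p = 0.0683), within a range of 0.00336 to 0.0952 over all alternatives by their own tests.

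The mast cell list was lower in gut nodes. Of 11 mast cell genes, 2 were higher and 7 lower (2 and 7 adjusted over the list alone), with camera adjusted p = 1.26e-15. Their median log2 fold change was -3.42. Granule proteases led the fall: Mcpt4, a connective tissue mast cell chymase, was at 0.238 ± 0.182 against 20.4 ± 7.33 CPM and Cpa3, the mast cell carboxypeptidase, at 0.557 ± 0.255 against 8.56 ± 2.63 CPM. Cma1 and the tryptase Tpsb2 had log2 fold changes of -3.68 ± 0.143 and -5.67 ± 0.331 (± SE). Of 14 macrophage genes, 5 were higher and 3 lower (5 and 3 adjusted over the list alone), with camera adjusted p = 0.137. Timd4, a phosphatidylserine receptor of resident macrophages, fell from 331 ± 19.5 CPM in inguinal to 34.3 ± 9.16 CPM in gut nodes, and Mrc1, the mannose receptor, fell less (-0.71 ± 0.104). Of 15 dendritic cell genes, 4 were higher and 4 lower (6 and 6 adjusted over the list alone), with camera adjusted p = 0.959. Clec9a, a receptor for dead cells on cross-presenting dendritic cells, was higher (106 ± 24.9 against 56.95 ± 5.81 CPM). Cd209a and Irf4, both of type 2 dendritic cells, were lower (-1.75 ± 0.163 and -0.65 ± 0.0718). Among the largest falls, the chemokine Ccl8 stood at 12.8 ± 18.2 against 242 ± 39.2 CPM and Cyp2f2, a cytochrome of xenobiotic metabolism, at 1.31 ± 1.13 against 31.5 ± 5.23 CPM. The largest adjusted p among these genes was 2.14e-05, for Mrc1, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

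Innate lymphocyte genes went both ways. Of 20 innate lymphoid and natural killer genes, 5 were higher and 7 lower (6 and 8 adjusted over the list alone), with camera adjusted p = 0.959. Il1rl1, the receptor of Il33, and Klrg1, both found on type 2 innate lymphoid cells, were higher in gut nodes (26.8 ± 8.91 against 7.503 ± 0.779 CPM and 12.99 ± 3.17 against 4.24 ± 0.742 CPM). Prf1, which encodes the pore-forming protein of cytotoxic cells, was lower (30.5 ± 5.72 against 49.9 ± 7.91 CPM). Of 11 granulocyte genes, 1 was higher and 2 lower (1 and 3 adjusted over the list alone), with camera adjusted p = 0.959. Prg2, an eosinophil granule protein, was higher (1.72 ± 0.218 on the log2 scale). Of 14 interferon response genes, 14 were higher and 0 lower (14 and 0 adjusted over the list alone), with camera adjusted p = 1.70e-08 and adjusted p = 0.347 with an estimated correlation. Their median log2 fold change was 0.96. Isg15, a ubiquitin-like modifier, stood at 119 ± 42.5 against 38.6 ± 11.2 CPM and the chemokine Cxcl10 at 122 ± 35.4 against 44.5 ± 10.2 CPM. These genes had adjusted p of 9.20e-06, for Isg15, or less in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

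Of 16 lipid uptake and export genes, 7 were higher and 3 lower (7 and 5 adjusted over the list alone), with camera adjusted p = 0.149. Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, was higher (1.54 ± 0.177 on the log2 scale). Of 10 class II antigen presentation genes, 4 were higher and 0 lower (5 and 0 adjusted over the list alone), with camera adjusted p = 0.196. H2-Oa was among the higher ones (0.60 ± 0.0995). Of 12 cell division genes, 2 were higher and 0 lower (0 and 0 adjusted over the list alone), with camera adjusted p = 0.235. Of 11 immediate early and stress genes, 5 were higher and 0 lower (5 and 0 adjusted over the list alone), with camera adjusted p = 0.07801. Zfp36, an RNA-binding protein that shortens cytokine messages, was at 0.40 ± 0.0605. Of 31 Hox genes, 4 were higher and 13 lower (4 and 14 adjusted over the list alone), with camera adjusted p = 6.58e-04 and adjusted p = 0.294 with an estimated correlation. Hoxc10 stood at 2.02 ± 2.86 against 6.78 ± 0.371 CPM, and Hoxc9 and Hoxa10 had log2 fold changes of -1.68 ± 0.0838 and -1.84 ± 0.122. The ceco-colonic node did not follow this mean: Hoxa10 was at 3.68 ± 0.547 CPM there and at 1.84 ± 0.118 CPM in the inguinal node, and Hoxc10 at 6.73 ± 0.468 and 6.78 ± 0.371 CPM. Hox genes in ceco-colonic against inguinal nodes had 5 of 31 higher and 7 lower (5 and 11 adjusted over the list alone), with camera adjusted p = 0.841.

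Of 14 adipocyte genes, 2 were higher and 2 lower (2 and 2 adjusted over the list alone), with camera adjusted p = 0.271. Of 17 pancreatic genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone), with camera adjusted p = 0.0843. Of 12 intestinal epithelial genes, 6 were higher and 1 lower (6 and 2 adjusted over the list alone), with camera adjusted p = 0.009004 and adjusted p = 0.121 with an estimated correlation. The cadherin gene Cdh17, of intestinal epithelium, stood at 1.67 ± 0.341 against 0.689 ± 0.0663 CPM. Of 8 keratinocyte and mammary epithelial genes, 1 was higher and 3 lower (1 and 3 adjusted over the list alone), with camera adjusted p = 0.233. Trp63, a basal epithelial factor, was at 1.21 ± 0.341 against 2.73 ± 0.6997 CPM. Of 9 skeletal muscle genes, 2 were higher and 2 lower (2 and 3 adjusted over the list alone), with camera adjusted p = 0.416. The myosin gene Myh2 was at 0.04395 ± 0.0276 against 0.437 ± 0.0604 CPM. Of 11 smooth muscle and mesothelial genes, 2 were higher and 3 lower (2 and 3 adjusted over the list alone), with camera adjusted p = 0.952. Wt1, a mesothelial transcription factor, was higher (1.47 ± 0.656 against 0.123 ± 0.0419 CPM). Of 8 glial and neuronal genes, 3 were higher and 2 lower (3 and 3 adjusted over the list alone), with camera adjusted p = 0.566. Prph, a neuronal filament gene, had a log2 fold change of -1.14 ± 0.105. Of 7 erythroid genes, 0 were higher and 4 lower (0 and 6 adjusted over the list alone), with camera adjusted p = 0.0413 and adjusted p = 0.63 with an estimated correlation. Hemgn, an erythroid nuclear factor, was at -0.97 ± 0.122. The median, the mean and the camera direction did not share 1 sign for macrophages, dendritic cells, granulocytes, innate lymphoid cells, keratinocytes, smooth muscle, and glia and neurons.

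Each gut node was also compared with the inguinal node by itself. The inguinal libraries are the same in all 4 comparisons, so no overlap between them is given. Nkx2-3 was higher at every gut position, with log2 fold changes (± SE) of 9.41 ± 0.181 in duodenal, 9.41 ± 0.181 in jejunal, 9.43 ± 0.181 in ileal and 9.44 ± 0.181 in ceco-colonic nodes. Madcam1 was at 4.26 ± 0.209, 3.70 ± 0.204, 4.11 ± 0.208 and 5.08 ± 0.217 in the same order, and Aldh1a2 at 2.92 ± 0.157, 3.14 ± 0.159, 3.49 ± 0.161 and 3.13 ± 0.158. Cxcl14, an epithelial and stromal chemokine, was among the 4 highest fold changes of called genes at 5 CPM or more in jejunal (21.3 ± 1.38 against 0.564 ± 0.2201 CPM; mean ± SD, n = 4 each) and ileal nodes (18.9 ± 3.77 against 0.564 ± 0.2201 CPM), and Lrrn2 in these and in ceco-colonic nodes (17.7 ± 1.79 against 0.519 ± 0.0422 CPM). Bpifb3, a secreted lipid-binding protein, was at 0.00685 ± 0.00842 CPM in duodenal, 0.00234 ± 0.00293 CPM in jejunal, 0.0155 ± 0.00734 CPM in ileal and 0.09196 ± 0.0446 CPM in ceco-colonic against 10.1 ± 2.804 CPM in inguinal nodes. Tbx15 stood at 0.0878 ± 0.0142 against 13.2 ± 1.98 CPM in ceco-colonic nodes. Lymphatic endothelial genes in duodenal nodes had 2 of 14 higher and 1 lower (3 and 2 adjusted over the list alone), with camera adjusted p = 0.942. In jejunal nodes they had 9 of 14 higher and 0 lower (12 and 0 adjusted over the list alone), with camera adjusted p = 4.03e-04 and adjusted p = 0.478 with an estimated correlation. In ileal nodes they had 11 of 14 higher and 1 lower (12 and 1 adjusted over the list alone), with camera adjusted p = 2.56e-05 and adjusted p = 0.373 with an estimated correlation. In ceco-colonic nodes they had 0 of 14 higher and 8 lower (1 and 9 adjusted over the list alone), with camera adjusted p = 0.00886 and adjusted p = 0.555 with an estimated correlation. Macrophage genes in duodenal nodes had 0 of 14 higher and 7 lower (1 and 8 adjusted over the list alone), with camera adjusted p = 4.79e-04 and adjusted p = 0.3604 with an estimated correlation. In jejunal nodes these had 7 of 14 higher and 2 lower (7 and 2 adjusted over the list alone), with camera adjusted p = 0.722. In ileal nodes these had 8 of 14 higher and 3 lower (9 and 3 adjusted over the list alone), with camera adjusted p = 0.286. In ceco-colonic nodes these had 1 of 14 higher and 6 lower (1 and 6 adjusted over the list alone), with camera adjusted p = 0.00301 and adjusted p = 0.548 with an estimated correlation. Adipocyte genes in jejunal nodes had 6 of 14 higher and 1 lower (8 and 1 adjusted over the list alone), with camera adjusted p = 0.01204 and adjusted p = 0.799 with an estimated correlation. In ileal nodes they had 6 of 14 higher and 1 lower (8 and 1 adjusted over the list alone), with camera adjusted p = 0.00518 and adjusted p = 0.593 with an estimated correlation. Pancreatic genes in duodenal nodes had 16 of 17 higher and 0 lower (17 and 0 adjusted over the list alone), with camera adjusted p = 8.56e-05 and adjusted p = 0.839 with an estimated correlation. Intestinal epithelial genes in duodenal nodes had 7 of 12 higher and 0 lower (7 and 1 adjusted over the list alone), with camera adjusted p = 0.00253 and adjusted p = 0.0615 with an estimated correlation. In jejunal nodes they had 6 of 12 higher and 0 lower (6 and 0 adjusted over the list alone), with camera adjusted p = 0.00106. In ileal nodes they had 6 of 12 higher and 1 lower (8 and 1 adjusted over the list alone), with camera adjusted p = 0.00162. Immediate early and stress genes in ileal nodes had 4 of 11 higher and 0 lower (6 and 0 adjusted over the list alone), with camera adjusted p = 0.02402 and adjusted p = 0.572 with an estimated correlation. In ceco-colonic nodes they had 5 of 11 higher and 0 lower (7 and 0 adjusted over the list alone), with camera adjusted p = 0.0191 and adjusted p = 0.555 with an estimated correlation. Erythroid genes in ileal nodes had 0 of 7 higher and 5 lower (0 and 6 adjusted over the list alone), with camera adjusted p = 0.01101 and adjusted p = 0.401 with an estimated correlation. In ceco-colonic nodes they had 0 of 7 higher and 4 lower (0 and 6 adjusted over the list alone), with camera adjusted p = 0.0172 and adjusted p = 0.548 with an estimated correlation. In numbers, 7429 genes changed in duodenal nodes (3868 higher and 3561 lower), 6157 in jejunal (3350 and 2807), 6648 in ileal (3687 and 2961) and 6168 in ceco-colonic nodes (3128 and 3040). The balance turned in duodenal nodes with limma-voom (52.1% against 49.6% higher) and in ceco-colonic nodes, from 50.7% to 48.2% with counts summed from transcripts, 49.97% and 48.7% without ceco-colonic library 1 or 3, and 48.9% and 49.5% without inguinal library 1 or 3. The largest adjusted p among the genes named was 6.05e-11, for Madcam1, in jejunal nodes, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

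Differences among the 4 gut nodes were then tested together, to ask whether nodes along the intestine differ from each other. Among genes at 5 CPM or more, the smallest p belonged to Hox genes, transcription factors that mark the body axis. Hoxa9 rose from 0.3899 ± 0.0694 CPM in duodenal over 1.05 ± 0.18 in jejunal and 1.91 ± 0.175 in ileal to 5.56 ± 0.468 CPM in ceco-colonic nodes (mean ± SD, n = 4 each). Hoxc9 rose from 0.665 ± 0.0958 over 1.59 ± 0.116 and 3.36 ± 0.579 to 5.18 ± 0.208 CPM. In the next genes the ceco-colonic node stood apart. Gzmc, a granzyme of killer lymphocytes, was at 20.03 ± 3.63 CPM there and at 2.61 to 4.81 CPM in the small intestinal nodes. Cx3cl1, the membrane-bound chemokine fractalkine, was at 68.3 ± 3.96 against 25.4 to 34.9 CPM, Serpinc1, which encodes antithrombin, at 22.8 ± 2.75 against 6.85 to 9.56 CPM, and Fcgr2b, the inhibitory receptor for antibody complexes, at 78.2 ± 5.43 against 35.8 to 40.1 CPM. Col6a6, a collagen chain, was at 2.16 ± 0.344 against 26.6 to 34.01 CPM and Ccl8 at 41.6 ± 13.4 against 2.24 to 4.55 CPM. In all, 6276 of 29411 genes (21.3%) differed. These 8 genes had adjusted p between 4.86e-11, for Hoxa9, and 1.05e-09, for Ccl8, in the F-test of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

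**Figure D3:**
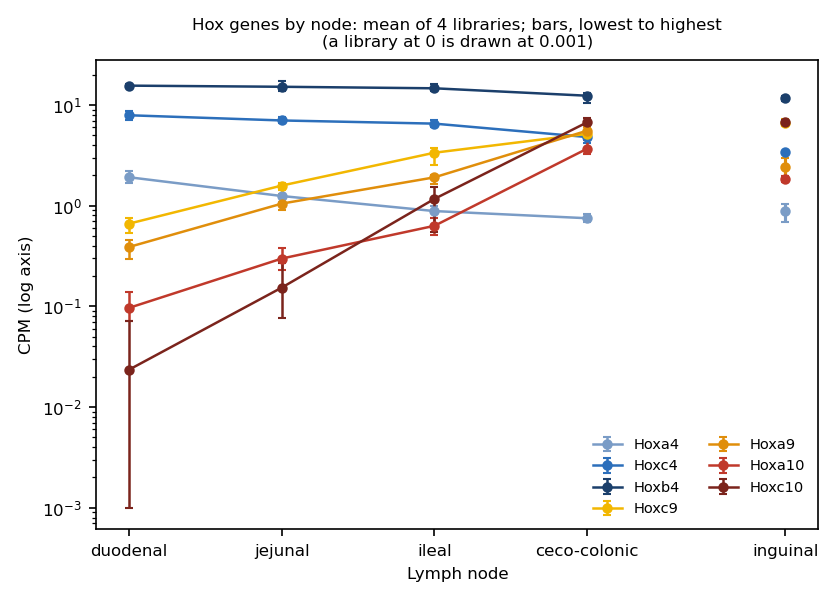
Levels of 7 Hox genes in CPM on a log axis (y) in the nodes of the 4 gut positions and, set apart, the inguinal node (x); points are means of 4 libraries and bars span the lowest to the highest library. Mean levels of Hoxa9, Hoxc9, Hoxa10 and Hoxc10 climb from the duodenal to the ceco-colonic node, whereas those of Hoxa4, Hoxb4 and Hoxc4, chosen after their values were seen, descend. Hoxd4, not drawn, goes the other way, with 6.72 CPM in duodenal and 10.57 CPM in ceco-colonic nodes.

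Small intestinal nodes, 12 libraries from duodenum, jejunum and ileum, were compared with the 4 ceco-colonic libraries, to ask what sets nodes of the small intestine apart. Lyve1, of lymphatic endothelium, was higher in small intestinal nodes (306 ± 98.4 against 108 ± 23.8 CPM; mean ± SD). So were Stab2, a scavenger receptor of sinus lining cells (266 ± 63.98 against 134 ± 23.97 CPM), and the transcription factor Tbx1 (51.1 ± 15.6 against 24.9 ± 3.501 CPM). Col6a6 was higher too (30.6 ± 7.34 against 2.16 ± 0.344 CPM; log2 fold change 3.81 ± 0.188 (SE)). Cd163, the hemoglobin scavenger receptor of macrophages, was also higher (26.5 ± 13 against 4.15 ± 1.28 CPM). Higher in ceco-colonic nodes were Hoxc10 (0.449 ± 0.587 against 6.73 ± 0.468 CPM), the matrix-degrading enzyme gene Mmp3 (8.701 ± 5.91 against 103 ± 27.8 CPM) and Ccl8 (3.16 ± 1.43 against 41.6 ± 13.4 CPM). Nkx2-3 (21.8 ± 1.77 against 22.2 ± 0.521 CPM) and Aldh1a2 (179 ± 44.1 against 169 ± 13.7 CPM) were not called. In all 4894 genes changed, 2618 higher and 2276 lower in small intestinal nodes, 1010 of them by at least 2-fold. With the mean level of adipocyte genes as a covariate the count was 3077. Adjusted p of the called genes lay between 5.67e-11, for Col6a6, and 5.21e-06, for Tbx1, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

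The lymphatic endothelial list was higher in small intestinal nodes. Of 14 lymphatic endothelial genes, 12 were higher and 0 lower (12 and 0 adjusted over the list alone), with camera adjusted p = 3.03e-15 and adjusted p = 0.07203 with an estimated correlation. Their median log2 fold change was 0.83. Of 14 macrophage genes, 6 were higher and 1 lower (6 and 1 adjusted over the list alone), with camera adjusted p = 0.00142 and adjusted p = 0.417 with an estimated correlation. Against the same ceco-colonic libraries, macrophage genes in duodenal nodes alone had 3 of 14 higher and 4 lower (3 and 5 adjusted over the list alone), with camera adjusted p = 0.533, and a median log2 fold change of -0.15. In jejunal nodes they had 6 of 14 higher and 1 lower (8 and 1 adjusted over the list alone), with camera adjusted p = 3.00e-06 and adjusted p = 0.187 with an estimated correlation. In ileal nodes they had 10 of 14 higher and 1 lower (12 and 1 adjusted over the list alone), with camera adjusted p = 2.34e-09 and adjusted p = 0.104 with an estimated correlation. Mrc1 stood at 157 ± 33.99 against 93.5 ± 12.7 CPM and Marco, which is on both lists, at 1296 ± 305 against 704 ± 83.6 CPM. Clec4g, a lectin of sinusoidal endothelium, rose by 2.30 ± 0.143 and Kcnk3, a potassium channel, by 2.60 ± 0.193 on the log2 scale (± SE). Of 20 retinoid genes, 8 were higher and 3 lower (8 and 4 adjusted over the list alone), with camera adjusted p = 0.0261 and adjusted p = 0.372 with an estimated correlation. Aldh1a1, another retinaldehyde dehydrogenase, was at 18.3 ± 7.71 against 4.58 ± 1.14 CPM, and Dhrs3 and Rarb were higher by 0.87 and 0.93. Of 10 medullary reticular genes, 3 were higher and 1 lower (3 and 1 adjusted over the list alone), with camera adjusted p = 0.249. Inmt, a methyltransferase of medullary reticular cells, was at 168 ± 27.6 against 70.7 ± 19.1 CPM, Il6 was lower at -0.85 ± 0.162 and Cxcl12 was not called at -0.09 ± 0.0642. Of 16 fibroblast and matrix genes, 4 were higher and 1 lower (4 and 2 adjusted over the list alone), with camera adjusted p = 0.0311 and adjusted p = 0.565 with an estimated correlation. Postn, which encodes periostin, was at 359 ± 37.3 against 123 ± 5.403 CPM, and the proteoglycan gene Dcn was higher by 0.61 ± 0.0734. Of 14 interferon response genes, 7 were higher and 0 lower (12 and 0 adjusted over the list alone), with camera adjusted p = 0.00259 and adjusted p = 0.565 with an estimated correlation. Genes of other tissues moved with these groups. Of 14 adipocyte genes, 3 were higher and 0 lower (9 and 0 adjusted over the list alone), with camera adjusted p = 0.001998 and adjusted p = 0.565 with an estimated correlation. Of 17 pancreatic genes, 9 were higher and 0 lower (16 and 0 adjusted over the list alone), with camera adjusted p = 0.00142 and adjusted p = 0.565 with an estimated correlation. The pancreatic level was highest in duodenal libraries 1 and 2.

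Ceco-colonic nodes carried more transcripts of granulocytes and of several dendritic cell and reticular cell genes. Of 11 granulocyte genes, 0 were higher and 7 lower (0 and 10 adjusted over the list alone), with camera adjusted p = 5.22e-09 and adjusted p = 0.07203 with an estimated correlation. Prg2 and Siglecf, both of eosinophils, were at 1.15 ± 0.444 against 3.77 ± 0.844 CPM and 1.01 ± 0.269 against 2.701 ± 0.857 CPM, and Cxcr2, the chemokine receptor of neutrophils, at 13.5 ± 2.33 against 23.6 ± 4.41 CPM. Of 15 dendritic cell genes, 1 was higher and 8 lower (2 and 10 adjusted over the list alone), with camera adjusted p = 4.58e-04 and adjusted p = 0.0976 with an estimated correlation. Irf4 and the integrin gene Itgae were lower in small intestinal nodes (27.7 ± 3.01 against 48.6 ± 3.92 CPM and 47.2 ± 5.01 against 75 ± 6.99 CPM) and Clec9a higher (118 ± 13.97 against 69.7 ± 7.43 CPM). Of 10 T-zone reticular genes, 0 were higher and 5 lower (1 and 5 adjusted over the list alone), with camera adjusted p = 0.00142 and adjusted p = 0.417 with an estimated correlation. The chemokine genes Ccl19 and Ccl21a had log2 fold changes of -0.59 ± 0.122 and -0.74 ± 0.162, and Tnfsf13b of -0.90 ± 0.0751. For Ccl21a, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.00279. With the adipocyte covariate it was 0.0505, in a range of 1.05e-04 to 0.0505 over the alternatives. Of 10 follicular and marginal reticular genes, 1 was higher and 4 lower (2 and 4 adjusted over the list alone), with camera adjusted p = 0.0738. Cxcl13 stood at 21.5 ± 13.02 against 70.05 ± 13.3 CPM, Madcam1 at 62.2 ± 17.5 against 128 ± 15.4 CPM and Sox9, a transcription factor of cartilage and epithelial progenitors, at 1.39 ± 0.508 against 0.513 ± 0.0972 CPM. Of 12 cell division genes, 0 were higher and 3 lower (0 and 3 adjusted over the list alone), with camera adjusted p = 0.003699 and adjusted p = 0.565 with an estimated correlation.

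Further groups went both ways. Of 15 blood endothelial genes, 4 were higher and 3 lower (4 and 3 adjusted over the list alone), with camera adjusted p = 0.997. Kdr, the main receptor of vascular endothelial growth factor, was higher in small intestinal nodes (0.67 ± 0.0774 on the log2 scale), and Glycam1 was not called (249 ± 140.4 against 213 ± 38.8 CPM). Of 20 innate lymphoid and natural killer genes, 3 were higher and 5 lower (4 and 8 adjusted over the list alone), with camera adjusted p = 0.517. Il1rl1 (31 ± 5.54 against 14.3 ± 2.49 CPM) was higher in small intestinal nodes. Eomes, a factor of natural killer cells, was lower there (-0.44 ± 0.0705). Cd3g, a chain of the T-cell receptor complex, was at 4.82 ± 1.04 against 2.599 ± 0.564 CPM, and Trac, another chain gene, at 1.56 ± 0.171 against 2.17 ± 0.184 CPM. Of 16 lipid uptake and export genes, 6 were higher and 3 lower (9 and 3 adjusted over the list alone), with camera adjusted p = 0.431. Trem2, a lipid receptor of macrophages, was lower (-0.99 ± 0.102) and Plin2, which coats lipid droplets, higher in small intestinal nodes (0.48 ± 0.0647). Of 31 Hox genes, 9 were higher and 14 lower (9 and 16 adjusted over the list alone), with camera adjusted p = 2.31e-10 and adjusted p = 0.07203 with an estimated correlation. Hoxa9, Hoxa10 and Hoxd11 had log2 fold changes of -2.59 ± 0.109, -3.79 ± 0.127 and -4.98 ± 0.242 (± SE). The positional factor Irx1 (0.787 ± 0.492 against 6.33 ± 0.954 CPM), the collagen hydroxylase gene P4ha3 (0.854 ± 0.3499 against 5.72 ± 0.367 CPM) and the granzyme gene Gzmc (3.55 ± 1.11 against 20.03 ± 3.63 CPM) were higher in ceco-colonic nodes too. Of 12 intestinal epithelial genes, 5 were higher and 2 lower (5 and 2 adjusted over the list alone), with camera adjusted p = 0.03103 and adjusted p = 0.209 with an estimated correlation. The adhesion gene Epcam was at 6.82 ± 0.499 against 4.09 ± 0.4098 CPM. In this comparison the median, the mean and the camera direction did not share 1 sign for blood endothelium, keratinocytes and skeletal muscle.

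**Figure D4:**
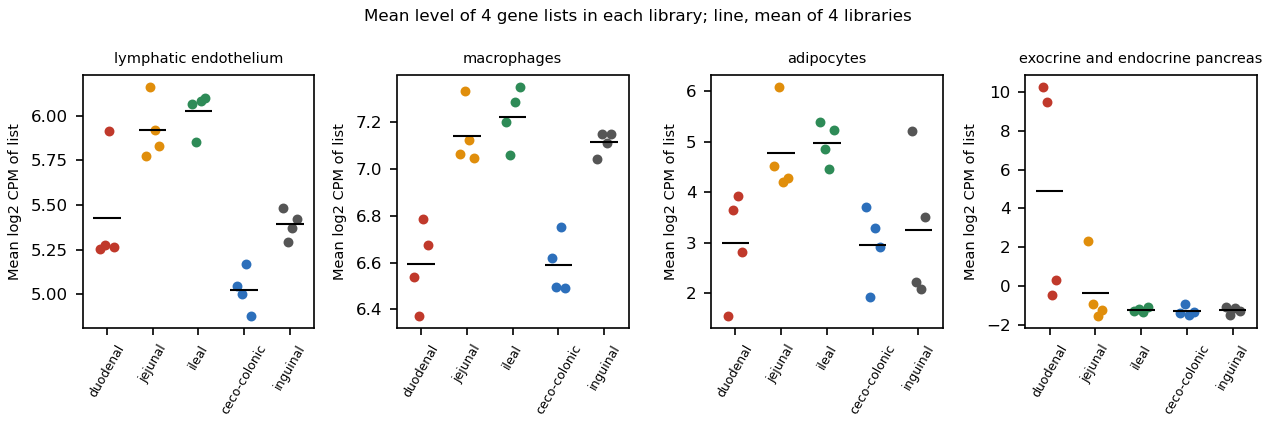
Mean log2 CPM of the genes of 4 lists (y axes) in each library of the 5 nodes (x), with a line at the mean of 4 libraries. Ceco-colonic libraries are the lowest for lymphatic endothelium, the adipocyte level varies within nodes, and the pancreas list stands out in duodenal libraries 1 and 2.

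The ends of the small intestine were compared through the duodenal and ileal nodes. Coch, a secreted protein of marginal stroma, was lower in duodenal nodes (4.07 ± 0.918 against 28.96 ± 3.86 CPM; mean ± SD, n = 4 each). So were Il22ra2, the soluble trap of the cytokine Il22 (2.03 ± 0.858 against 13.1 ± 2.03 CPM), and Il22 itself (0.1303 ± 0.143 against 2.71 ± 1.15 CPM). Cd5l, a secreted protein of resident macrophages, was at 204 ± 33.4 against 490.5 ± 70.1 CPM, and the complement gene C1qc at 416 ± 41.1 against 642 ± 60.5 CPM. Glycam1 of high endothelial venules (401 ± 22.5 against 120.5 ± 35.01 CPM) and Cd8a (40.6 ± 7.39 against 17.1 ± 1.04 CPM) were higher in duodenal nodes. In all 4297 genes changed, 1935 higher and 2362 lower in duodenal nodes, whereas of those changed by at least 2-fold 584 were higher and 225 lower. The balance of all calls turned with the setting: 45.0% were higher with edgeR, 52.0% with counts summed from transcripts, 50.4% with no filter on low counts, 53.6% without duodenal libraries 1 and 2, and 51.0% and 51.5% without duodenal library 2 or 4. The count was 2306 without duodenal library 2, 2553 without ileal library 3 and 2427 without ileal library 4. It was 1267 without duodenal libraries 1 and 2, 2239 with the adipocyte covariate and 2571 when only these 8 libraries were fitted.

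The macrophage list was lower in duodenal than in ileal nodes. No list was retested without duodenal libraries 1 and 2. Of 14 macrophage genes, 0 were higher and 10 lower (0 and 12 adjusted over the list alone), with camera adjusted p = 1.80e-13. Of 14 lymphatic endothelial genes, 0 were higher and 8 lower (0 and 10 adjusted over the list alone), with camera adjusted p = 3.53e-11 and adjusted p = 0.0841 with an estimated correlation. Tbx1 and Stab2 had log2 fold changes of -0.93 ± 0.138 and -0.71 ± 0.13 (± SE). Of 16 lipid uptake and export genes, 0 were higher and 9 lower (0 and 12 adjusted over the list alone), with camera adjusted p = 1.24e-08. Plin2 was at -0.51 ± 0.0772. Of 17 lymphocyte genes, 7 were higher and 0 lower (7 and 1 adjusted over the list alone), with camera adjusted p = 3.18e-06 and adjusted p = 0.0841 with an estimated correlation. Ms4a1 was at 1.10 ± 0.122 and Jchain, which joins antibody chains, at 1.51 ± 0.264. Of 11 granulocyte genes, 7 were higher and 0 lower (7 and 0 adjusted over the list alone), with camera adjusted p = 3.51e-05 and adjusted p = 0.161 with an estimated correlation. Xcr1, a chemokine receptor of cross-presenting dendritic cells, was higher in duodenal nodes (0.93 ± 0.118). So was Cd34, of adventitial fibroblasts and vessels (0.72 ± 0.119), whereas Frzb, an inhibitor of Wnt signalling, was lower (-2.25 ± 0.205). Of 31 Hox genes, 6 were higher and 12 lower (8 and 15 adjusted over the list alone), with camera adjusted p = 3.34e-08. Hoxc9 and Hoxa9 were at -2.33 ± 0.126 and -2.29 ± 0.159. Genes of both paragraphs had adjusted p of 0.00188, for Glycam1, or less in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

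Tissue and stress lists follow. Of 14 adipocyte genes, 0 were higher and 8 lower (0 and 12 adjusted over the list alone), with camera adjusted p = 8.64e-08 and adjusted p = 0.303 with an estimated correlation. Of 17 pancreatic genes, 16 were higher and 0 lower (16 and 0 adjusted over the list alone), with camera adjusted p = 2.73e-10 and adjusted p = 0.263 with an estimated correlation. The chymotrypsinogen gene Ctrb1 was at 2941 ± 3683 against 0.541 ± 0.113 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment its adjusted p was 0.00164, against 0.293 without duodenal libraries 1 and 2 and 0.228 with limma-voom, in a range of 6.08e-16 to 0.293 over the alternatives. Of 8 glial and neuronal genes, 5 were higher and 0 lower (8 and 0 adjusted over the list alone), with camera adjusted p = 4.37e-07. The glial calcium-binding gene S100b stood at 2.01 ± 1.02 against 0.417 ± 0.195 CPM. Of 11 smooth muscle and mesothelial genes, 5 were higher and 4 lower (5 and 4 adjusted over the list alone), with camera adjusted p = 0.507. Of 11 immediate early and stress genes, 0 were higher and 2 lower (0 and 3 adjusted over the list alone), with camera adjusted p = 0.0286 and adjusted p = 0.542 with an estimated correlation. Of 8 keratinocyte and mammary epithelial genes, 2 were higher and 0 lower (3 and 0 adjusted over the list alone), with camera adjusted p = 0.0329 and adjusted p = 0.152 with an estimated correlation. Of 7 erythroid genes, 2 were higher and 0 lower (2 and 0 adjusted over the list alone), with camera adjusted p = 0.0471 and adjusted p = 0.499 with an estimated correlation.

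Duodenal and ceco-colonic nodes, from the ends of the gut sampled here, were compared next. Tnfsf4, which encodes the costimulator Ox40 ligand, was lower in duodenal nodes (1.404 ± 0.375 against 12.5 ± 2.41 CPM; mean ± SD, n = 4 each), as was Il22ra2 (2.03 ± 0.858 against 18.3 ± 7.99 CPM). Ccl8 (-4.22 ± 0.293 on the log2 scale, ± SE), Mmp3 (-4.00 ± 0.385) and the posterior Hox genes Hoxc10 (-8.02 ± 0.516) and Hoxa10 (-5.22 ± 0.207) were lower too. Trem2 and the cholesterol exporter gene Abcg1 were at -1.24 ± 0.134 and -0.85 ± 0.153, and the dendritic cell genes Irf4 and Itgae at -0.88 ± 0.0955 and -0.72 ± 0.089. Aldh1a1 (24.7 ± 9.93 against 4.58 ± 1.14 CPM) and Cd3g (5.6 ± 0.926 against 2.599 ± 0.564 CPM) were higher in duodenal nodes. Of 15 dendritic cell genes, 3 were higher and 9 lower (3 and 10 adjusted over the list alone), with camera adjusted p = 8.92e-04 and adjusted p = 0.241 with an estimated correlation. Of 14 lymphatic endothelial genes, 8 were higher and 0 lower (10 and 0 adjusted over the list alone), with camera adjusted p = 6.26e-04 and adjusted p = 0.483 with an estimated correlation. Of 8 glial and neuronal genes, 5 were higher and 0 lower (5 and 1 adjusted over the list alone), with camera adjusted p = 0.00183 and adjusted p = 0.349 with an estimated correlation. Of 17 pancreatic genes, 16 were higher and 0 lower (16 and 0 adjusted over the list alone), with camera adjusted p = 1.21e-07 and adjusted p = 0.483 with an estimated correlation. The pancreatic median log2 fold change was 11.83, with the highest levels in duodenal libraries 1 and 2. In all 4825 genes changed, 2422 higher and 2403 lower. The share of higher calls was 50.2% with edgeR, 47.9% with size factors of the DESeq2 type, 48.5% with DESeq2 and 47.4% with limma-voom. With all libraries this is the highest count of the 6 pairs of gut nodes, but it was 3036 without duodenal libraries 1 and 2, below the 4049 of ileal and 3958 of jejunal against ceco-colonic nodes. When only the 8 libraries of a pair were fitted it was 3113, below the 4207 of ileal against ceco-colonic nodes. The named genes had adjusted p of 6.09e-04, for Abcg1, or less in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

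Fewer genes separated duodenal from jejunal nodes. P2rx1, an ATP-gated channel of smooth muscle and platelets, was higher in duodenal nodes (8.92 ± 5.36 against 1.15 ± 0.368 CPM; mean ± SD, n = 4 each), as was Susd5, a hyaluronan-binding membrane protein (12.2 ± 12.5 against 0.224 ± 0.0607 CPM). Macrophage genes had 0 of 14 higher and 10 lower (0 and 12 adjusted over the list alone), with camera adjusted p = 2.84e-16. Lipid genes had 0 of 16 higher and 5 lower (0 and 11 adjusted over the list alone), with camera adjusted p = 2.12e-10. Lymphatic endothelial genes had 0 of 14 higher and 8 lower (0 and 9 adjusted over the list alone), with camera adjusted p = 4.63e-13 and adjusted p = 0.0853 with an estimated correlation. Among tissue genes, adipocyte genes had 0 of 14 higher and 1 lower (0 and 12 adjusted over the list alone), with camera adjusted p = 2.12e-10 and adjusted p = 0.189 with an estimated correlation. Glial genes had 3 of 8 higher and 0 lower (7 and 0 adjusted over the list alone), with camera adjusted p = 1.64e-09. Pancreatic genes had 16 of 17 higher and 0 lower (16 and 0 adjusted over the list alone), with camera adjusted p = 1.60e-14 and adjusted p = 0.167 with an estimated correlation. Smooth muscle and mesothelial genes had 5 of 11 higher and 0 lower (5 and 4 adjusted over the list alone), with camera adjusted p = 0.02901 and adjusted p = 0.343 with an estimated correlation. Keratinocyte and mammary epithelial genes had 2 of 8 higher and 0 lower (2 and 0 adjusted over the list alone), with camera adjusted p = 0.0279 and adjusted p = 0.134 with an estimated correlation. Immediate early and stress genes (median log2 fold change -0.19) had 0 of 11 higher and 0 lower (0 and 0 adjusted over the list alone), with camera adjusted p = 0.0491 and adjusted p = 0.557 with an estimated correlation. In all 831 genes changed, 378 higher and 453 lower in duodenal nodes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 2.68e-04 for P2rx1 and 0.00593 for Susd5. These became 0.109 and 0.168 when only these 8 libraries were fitted, and 0.0982 for Susd5 with limma-voom, in ranges of 8.18e-14 to 0.109 and 3.66e-08 to 0.168 over the alternatives. The count was 207 without duodenal library 2, 502, 447 and 421 without jejunal library 2, 3 or 4, and 113 without duodenal libraries 1 and 2. With only these 8 libraries edgeR called 0 genes, and 3378 had an unadjusted p under 0.05, while with all libraries DESeq2 called 1694 and limma-voom 513. With the adipocyte covariate edgeR called 509. The balance of directions turned with the setting: 45.5% of the calls were higher in duodenal nodes with edgeR, 34.7% with limma-voom, 51.2% with counts summed from transcripts, 54.4% with no filter on low counts, 73.1% with the adipocyte covariate and 85.0% without duodenal libraries 1 and 2. It was 59.3%, 62.8% and 55.1% without duodenal library 1, 2 or 4 and 57.8% without jejunal library 2.

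Few genes separated jejunal from ileal nodes. Sqle, which encodes squalene epoxidase of sterol synthesis, was higher in jejunal nodes (28.7 ± 0.454 against 19.6 ± 2.26 CPM; mean ± SD, n = 4 each). So was Stard4, a sterol transfer protein (38.97 ± 3.002 against 28.9 ± 1.36 CPM). Coch (7.48 ± 0.4202 against 28.96 ± 3.86 CPM) and Ms4a8a (-0.78 ± 0.109 on the log2 scale, ± SE) were lower. Interferon response genes had 0 of 14 higher and 0 lower (0 and 0 adjusted over the list alone), with camera adjusted p = 1.37e-08 and adjusted p = 0.498 with an estimated correlation. Pancreatic genes (median log2 fold change 2.71) had 0 of 17 higher and 0 lower (0 and 0 adjusted over the list alone), with camera adjusted p = 0.0173 and adjusted p = 0.818 with an estimated correlation. In all 20 genes changed, 6 higher and 14 lower in jejunal nodes, and 1594 had an unadjusted p under 0.05. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.0218 for Sqle, 0.00389 for Stard4, 0.00179 for Coch and 0.00477 for Ms4a8a. When only these 8 libraries were fitted, the calls of Sqle, Stard4 and Ms4a8a were lost (adjusted p = 0.0808, 0.113 and 0.0634). With counts summed from transcripts Stard4 lost its call (adjusted p = 0.117). Sqle lost it without ileal library 1, 2 or 3 or jejunal library 1 (adjusted p = 0.0528, 0.0775, 0.0734 and 0.0752). Over the alternatives adjusted p ranged over 1.87e-05 to 0.0808 for Sqle, 1.67e-08 to 0.117 for Stard4 and 1.67e-08 to 0.0634 for Ms4a8a. The count was 2 when only these 8 libraries were fitted, 96 with DESeq2, 8, 10 and 10 without ileal library 1, 2 or 4 and 7 without jejunal library 1.

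Jejunal and ileal nodes each differed from the ceco-colonic node. Col6a6 was higher in both, at 34.01 ± 8.86 against 2.16 ± 0.344 CPM for jejunal and 31.3 ± 5.88 against 2.16 ± 0.344 CPM for ileal nodes (mean ± SD, n = 4 each). Cd163 was at 39.2 ± 15.9 against 4.15 ± 1.28 CPM in the jejunal and Lyve1 at 371 ± 44.96 against 108 ± 23.8 CPM in the ileal comparison. Hoxc10 (-5.47 ± 0.42 on the log2 scale, ± SE) and Mmp3 (-4.00 ± 0.384) were lower in jejunal nodes, and Mmp3 (-2.97 ± 0.366) and Ccl8 (-3.19 ± 0.278) in ileal nodes. In jejunal nodes lymphatic endothelial genes had 11 of 14 higher and 0 lower (12 and 0 adjusted over the list alone), with camera adjusted p = 1.05e-19 and adjusted p = 0.0875 with an estimated correlation. In ileal nodes they had 12 of 14 higher and 0 lower (12 and 0 adjusted over the list alone), with camera adjusted p = 1.55e-24. Granulocyte genes in jejunal nodes had 0 of 11 higher and 6 lower (0 and 8 adjusted over the list alone), with camera adjusted p = 4.73e-08 and adjusted p = 0.133 with an estimated correlation. In ileal nodes these had 0 of 11 higher and 10 lower (0 and 10 adjusted over the list alone), with camera adjusted p = 7.92e-12. Adipocyte genes in jejunal nodes had 7 of 14 higher and 0 lower (13 and 0 adjusted over the list alone), with camera adjusted p = 1.48e-05 and adjusted p = 0.405 with an estimated correlation. In ileal nodes these had 8 of 14 higher and 0 lower (13 and 0 adjusted over the list alone), with camera adjusted p = 1.72e-06 and adjusted p = 0.292 with an estimated correlation. Intestinal epithelial genes in jejunal nodes had 5 of 12 higher and 2 lower (5 and 2 adjusted over the list alone), with camera adjusted p = 0.0256 and adjusted p = 0.187 with an estimated correlation. In ileal nodes these had 5 of 12 higher and 1 lower (5 and 2 adjusted over the list alone), with camera adjusted p = 0.0203 and adjusted p = 0.152 with an estimated correlation. In all 3586 genes changed between jejunal and ceco-colonic nodes (2099 higher and 1487 lower) and 3750 between ileal and ceco-colonic nodes (2186 and 1564). With the adipocyte covariate the counts were 1892 and 1663. The named genes had adjusted p of 1.18e-05, for Mmp3, or less in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.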

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

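Tests chosen only after the result was seen were those of a wrong label and of expression by the duodenal node for the pancreatic enzymes, those of fat and of skin for the mast cell genes, and the choice of 1 pair of nodes per gene below. The adipocyte covariate and the fit without duodenal libraries 1 and 2, used for the lymphatic genes, were also chosen after the data were seen, though before these tests were run.

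Pancreatic enzyme genes stood out in duodenal libraries 1 and 2, and no gene of that list is on another list used here. Pieces of pancreas are a candidate source: across 16 acinar genes the excess over the ileal mean had rank correlations of 0.991 between the 2 libraries and of 0.924 and 0.935 with jejunal library 1. Libraries of pancreas under a node's label are argued against by T-zone reticular genes, whose median log2 difference from duodenal libraries 3 and 4 was -0.0421 (-0.17 to 0.28 over 10 genes). Expression by the duodenal node as such is argued against by the ratio of the lower of libraries 1 and 2 to the higher of libraries 3 and 4, with a median of 1150.0 over the genes (190.8 to 1869). How the transcripts entered these libraries stays open.

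Lymphatic endothelial genes were lower in ceco-colonic than in small intestinal nodes, with 12 called and a median log2 fold change of 0.90 over these. Fat around the node as the whole cause is argued against, since 11 of the 12 stayed called with the adipocyte level as a covariate (median 0.76). Pancreatic tissue is argued against as well, since 12 of 12 stayed called without duodenal libraries 1 and 2 (median 0.95). Scaling to a shifted gene median stays open: size factors of the DESeq2 type gave a median of 0.896, but they rest on the typical gene as TMM does and moved the median of all genes from 0.00638 to -0.00106 only, so they test no such shift. A difference in lymphatic vessels or sinuses between these nodes stays open as well and was not tested.

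Mast cell protease genes were higher in inguinal nodes. Subcutaneous fat around the node is argued against, since over the 4 inguinal libraries the slope of the log2 level on the adipocyte level had a median of -0.0209 (-0.18 to 0.0559) over 7 called genes. Epidermis is argued against by the highest ratio of its abundant Krt14 or Krt5 to Mcpt4 in any inguinal library, 0.00321. Other skin layers were not tested. More mast cells in or at the capsule of the skin-draining node may explain the pattern, a hypothesis, as cell numbers were not tested.

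In each comparison, fitted with all libraries, only the real split gave as many changed genes, a share under 0.05. With 35 splits the smallest share is 1 of 35, unadjusted over 13 comparisons, so chance is not excluded for all jointly. The splits ignore what same-number libraries may share. With 100 splits drawn, the F-test among gut nodes called 6276 genes against at most 725 in another split, gut-draining against inguinal 7724 against 423, and small intestinal against ceco-colonic 4894 against 1102. With 35 splits, comparisons with inguinal called 7429 against 3 (duodenal), 6157 against 0 (jejunal), 6648 against 0 (ileal) and 6168 against 1 (ceco-colonic). Among pairs of gut nodes, duodenal and jejunal gave 831 against 369, duodenal and ileal 4297 against 349, duodenal and ceco-colonic 4825 against 828, jejunal and ileal 20 against 9, jejunal and ceco-colonic 3586 against 1, and ileal and ceco-colonic 3750 against 0.

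In 27 of 575 groups of 4 libraries (4.70%, against 5% by chance), 1 library lay apart in log2 CPM by more of the group's range than Dixon's critical value for 4 samples allows. The number per library was highest in inguinal library 1, duodenal library 1 and jejunal library 2, with 3 each. Among duodenal libraries these were, with the gap as a share of the range, Il6 (0.84), Isg15 (0.836) and Prg2 (0.938) highest in library 1, Trac (0.941) and Trem2 (0.834) lowest in library 2, and Mup22 (1, the others at 0) and Kdr (0.902) highest in library 3. Among jejunal libraries they were Clec4g (0.874) highest and Madcam1 (0.906) and Cxcr2 (0.835) lowest in library 2, and Cpa3 (0.946) and Il22ra2 (0.876) lowest in library 4. Among ileal libraries they were Nkx2-3 (0.927) lowest in library 2, Serpinc1 (0.933) lowest and Mup22 (1, the others at 0) highest in library 3, and Glycam1 (0.946) and Ccl19 (0.856) lowest in library 4. Among ceco-colonic libraries they were Ccl21a (0.895) highest in library 2, Gpnmb (0.867) highest and Il6 (0.852) lowest in library 3, and Cyp26b1 (0.864) highest in library 4. Among inguinal libraries they were Clec9a (0.867) and Bpifb3 (0.83) highest and Fn1 (0.848) lowest in library 1, Eomes (0.91) highest and Mfap4 (0.927) lowest in library 2, and Cdh17 (0.872) highest in library 4.

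For 20 of the 114 genes given here, 2 gut nodes differed from the inguinal node in opposite directions, both called, and the difference between the 2 gut nodes was itself called in edgeR. Each gene is given once, with the pair of nodes that differed most. Higher than inguinal in ceco-colonic and lower in duodenal nodes were Hoxa10 (log2 difference, duodenal less ceco-colonic, -5.22), Mmp3 (-4.00), Hoxa9 (-3.83), Tnfsf4 (-3.16), Cx3cl1 (-1.43) and Trem2 (-1.24). The reverse held for Aldh1a1 (2.43), Sox9 (1.93) and Cd3g (1.11). Lower than inguinal in ceco-colonic nodes were also, against higher levels in jejunal nodes, Cd163 (3.24), Kcnk3 (2.81), Clec4g (2.47) and Postn (1.57), and against higher levels in ileal nodes, Lyve1 (1.78), Tbx1 (1.40), Stab2 (1.23) and Kdr (0.79). Between duodenal and ileal nodes the genes were P2rx1 (3.15, higher in duodenal), Coch (-2.83) and C1qc (-0.62, both higher in ileal).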

How the results depend on the processing

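Leaving out duodenal libraries 1 and 2 and the adipocyte covariate were chosen only after the results were seen. Of 186 gene results given here 179 were called, and 172 of these kept their call under every alternative chosen beforehand. Losses numbered 6 under such an alternative other than leaving out 1 library, 2 when 1 library was left out, 1 without duodenal libraries 1 and 2, 2 with the adipocyte covariate and 0 with the replicate block, and no result changed sign. The genes were chosen partly with this known, and the full set the naming rule gives was less stable. Of its 651 results 506 were called, 382 kept their call under every alternative chosen beforehand, 84 lost it under one other than leaving out 1 library, 78 when 1 library was left out, 81 without duodenal libraries 1 and 2, 53 with the adipocyte covariate and 8 with the replicate block, and 6 changed sign.

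Size factors of the DESeq2 type, no filter on low counts and counts summed from transcripts moved no count of changed genes by more than 1.5-fold. With the adipocyte covariate the count was 3077 for small intestinal against ceco-colonic, 509 for duodenal against jejunal, 2239 for duodenal against ileal, 1892 for jejunal against ceco-colonic and 1663 for ileal against ceco-colonic nodes. Without duodenal libraries 1 and 2 it was 113 for duodenal against jejunal, 1267 for duodenal against ileal and 3036 for duodenal against ceco-colonic nodes, where fewer libraries are compared. With only the groups compared it was 2571 for duodenal against ileal, 3113 for duodenal against ceco-colonic and 2 for jejunal against ileal nodes. For duodenal against jejunal nodes edgeR then called 0, while with all libraries DESeq2 called 1694 and limma-voom 513. DESeq2 called 96 between jejunal and ileal nodes. Other than by construction where libraries were removed, the cause was not tested.

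Leaving out 1 library moved 3 counts by more than 1.5-fold. Duodenal against jejunal ranged from 207 (without duodenal library 2) to 1175 (without duodenal library 3). Duodenal against ileal ranged from 2306 (without duodenal library 2) to 4307 (without duodenal library 3). Jejunal against ileal ranged from 7 (without jejunal library 1) to 21 (without jejunal library 2).

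What the replicate numbers stand for is not given in the sources used here, and the libraries were not treated as pairs, since pairing was to be used only if every pair of libraries with the same number had a correlation over 0.1. Over 40 pairs of libraries with the same number, deviations from the node means had a median correlation of 0.075 (-0.0863 to 0.357), with 13 over 0.1, and pairs with different numbers had a median of -0.0209. For 17 of 20 libraries the own number had the highest mean correlation. Libraries with the same number thus appear to share something the main fit leaves out. The replicate block raised every gene count, as from 831 to 1597 for duodenal against jejunal and 20 to 38 for jejunal against ileal nodes.

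Of 324 list results 129 were called, and 19 of these stayed called with an estimated correlation, so most list calls rest on the preset correlation. Over all list results that alternative left 110 weaker and 214 the same. With fry 25 were weaker, 36 stronger and 263 the same, and with camera and the replicate block 9, 13 and 302. The share of variance between positions was 51.4% over the 500 most variable genes and 44.2% with a prior count of 0.5 among 20 libraries, and 40.4% and 34.8% among the 16 gut libraries. Depth leaves few counts for the lowest levels given, and most 2-fold but fewer 1.5-fold changes were recovered in simulated data.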

Other observations

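The Hox test by number was chosen only after the result was seen.

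Of 9 Hox genes with paralogue numbers 9 to 13, 9 were higher in ceco-colonic than duodenal nodes and 0 lower in edgeR. Of 8 numbered 6 to 8, 2 were higher and 1 lower, and of 14 numbered 1 to 5, 2 and 6. Across 31 genes the rank correlation of number with the ceco-colonic over duodenal log2 fold change was 0.681 (Pearson 0.668). Its two-sided permutation p, 4e-05 (1e+05 resamples), counts linked genes as independent. Correlations for jejunal and ileal less ceco-colonic were -0.391 and -0.257. Stromal cells of a node may carry the positional code of the gut segment it drains, a hypothesis from the same data.

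Jejunal nodes had more Sqle and Stard4 than ileal nodes, both genes of sterol handling. Calls of this kind led to a test of genes of sterol synthesis not named for that comparison. Of 19 such genes 16 were higher in jejunal nodes, and edgeR called 0, with 9 at an unadjusted p under 0.05. Camera gave p = 2.36e-09, and p = 0.0161 with an estimated correlation. The median log2 fold change was 0.199, at the bound of 0.2 set beforehand, so this test leaves open whether the pathway as a whole is higher.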
